A study of Mus musculus with 6 samples.

How the data were processed

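The analysis used the deposited raw UMI count matrices of the 6 libraries, whose unit is counts per gene and cell. It also used the authors' deposited cell metadata, which give counts of UMIs and of detected genes per cell. The other deposited labels, batch number, cluster number, cell type, library and behavioural response, were taken as the authors gave them, per the file headers. Per the labels' protocols, cells were dissociated from hippocampi without meninges and choroid plexus, enriched on Percoll and sorted for live CD45-positive cells. Per the submitters' processing notes, Cell Ranger 2.2.0 and Seurat 2.3.4 were used with genome build mm10. How cells were filtered, clustered and typed, and what defined a batch, is not given in the sources used here. The deposited normalized matrices and the merged copies were not used here. UMI sums per cell equalled the deposited totals in all 3005 cells. Xist had 0 UMIs in every library, and Ddx3y had 123, 153, 127, 158, 30 and 118 UMIs in microglia of the non-shocked, acute non-helpless, acute helpless, chronic non-helpless, non-recovered and recovered libraries.

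Shares of cells were given exact Clopper-Pearson intervals. Raw UMIs were summed per library and deposited cell type and scaled by that sum, as CPM. The ratio of 2 libraries was given a conditional exact interval. In log2 ratios, and so in the ranking of genes and the list medians, a count of 0, 1 or 2 in the lower library was set to 3. A fold is the ratio of the counts as they are, except that for a count of 0 it is the value at 3 counts, given as a lower bound. Cell types other than microglia were compared where both libraries of 1 of the 9 comparisons had at least 20 cells. Named genes were the 12 with the highest and the 12 with the lowest ratio among genes with at least 50 CPM and 30 UMIs in the higher library, and members of the gene lists at least 1.5-fold apart. Mitochondrially encoded, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor genes, unnamed gene models, Xist and Y-linked genes were left out of the named genes. The levels of single genes given per library or per batch were chosen after their values were seen.

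Each of 23 gene lists was described by the median log2 ratio of its members with at least 20 CPM in the higher library, where at least 5 were measured. Its percentile came from 10000 random lists of the same size, matched in 20 bins of mean expression. A percentile describes these libraries and is no test between groups. The lists were microglia homeostatic, disease-associated microglia, interferon response, inflammatory cytokines and chemokines, NF-kB feedback and targets, immediate early and dissociation genes, heat shock, glucocorticoid response, MHC class II presentation, MHC class I presentation, complement and Fc receptors, lysosome and phagocytosis, purinergic and neurotransmitter sensing, glycolysis and hypoxia, nuclear oxidative phosphorylation, mitochondrially encoded, proliferation, lipid and cholesterol handling, Th17 and IL-17 axis, T cell activation and effector, naive and recirculating T cell, monocyte entry and adhesion, and growth factors and resolution.

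The comparisons, lists, naming rule and first set of alternatives were chosen before the data were examined. That set held Leiden clusters in place of the deposited cell types (2000 variable genes, 30 components, 15 neighbours, resolution 1.0), Scrublet doublets removed (20 components per library), cells with at least 1000 UMIs and cells with under 5% mitochondrial UMIs. For ratios and lists it held median-of-ratios size factors, each cell weighted equally, cells thinned to 1000 UMIs, totals without mitochondrial and ribosomal protein genes, list minima of 5 and 50 CPM and the mean in place of the median. Doublets were kept in the main analysis, since Scrublet called 56 of 3005 cells, 6 of them among the 161 T cell barcodes. Leiden clusters were named where at least 3 markers of a type were detected in 20% of cells and 2-fold above the other cells.

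Further alternatives were chosen after seeing the data. T cell barcodes with at least 0.5% of their UMIs in 7 microglial markers, P2ry12 and Tmem119 among them, were left out. Non-shocked cells were limited to the batch of the other library. Older and newer symbols of a gene were merged for 257 pairs, and 310 symbols found under only 1 of the annotations were left out. A marker check left out 15 of 2721 microglia with under 0.5% of these markers or at least 20 UMIs of 7 neutrophil genes. Microglia were also limited to those with at least 2.5% ribosomal protein UMIs. Genes in the group of 193 were those at least 1.5-fold higher in each of 3 libraries than in each of the other 3, with 2 CPM added and only batch 3 for non-shocked cells, among 4181 genes. It was also found without non-shocked cells, to compare their batches with 10000 draws of other genes matched in 20 bins of level. GC content was taken from the first 400 nt of GENCODE M21 transcripts.

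The methods were tested on simulated data drawn from these libraries with known changes. Genes raised or lowered 2-fold and 4-fold were recovered at medians of 1.95 to 2.05 and 3.95 to 4.10, with 100 of 100 in the right direction, and intervals held the true ratio for 95.3% to 96.9% of genes. The known shift in total counts was taken out of these folds. Counts were Poisson draws from 1 profile per comparison, the model that the intervals assume. They had no spread between cells, mice or libraries, so the coverage checks the calculation and not the error in real data. Raised lists lay at percentile 100 and unchanged lists between 1.1 and 96.5, so that 1 of 9 unchanged lists fell outside the central 95%. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.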

Results

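Live CD45-positive cells sorted from mouse hippocampi were profiled by droplet-based 5' single-cell RNA sequencing in 6 groups of the learned helplessness paradigm, in which inescapable foot shocks precede a test of escape. The labels give 180 inescapable shocks of 0.3 mA and a test of 30 trials lasting 24 s each. Mice of the acute paradigm were divided into helpless and non-helpless animals. In the chronic paradigm, with weekly retests for 3 weeks, they were divided into non-helpless, non-recovered and recovered animals, the last being mice that were helpless at first and later were not. A non-shocked group served as the control. Each group had 1 library, so no spread between replicates exists and no test between groups was possible. Intervals of shares, of levels and of ratios of single genes are exact 95% intervals and cover counting error only. Intervals of medians over genes, given in the closing part, are the central 95% of repeated draws of genes and do not measure counting error.

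The deposited data held 3005 cells and 14097425 UMIs, with a median of 4135 UMIs per cell. The non-shocked library had 586 cells and 2169073 UMIs, the acute non-helpless library 586 cells and 2429663 UMIs, and the acute helpless library 687 cells and 3160102 UMIs. The chronic non-helpless library had 547 cells and 2639690 UMIs and the chronic recovered library 478 cells and 3260120 UMIs. The chronic non-recovered library was the smallest, with 121 cells and 438777 UMIs. The authors' batch numbers place the acute helpless library in batch 1, the acute non-helpless library in batch 2 and the 3 chronic libraries in batch 3. Non-shocked cells came from batch 2 (128 cells) and batch 3 (458 cells). The acute helpless library therefore shared no batch with any other library, and its group and its batch cannot be told apart.

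Which immune cells the hippocampus held in each group was read from the authors' cell types. Microglia, the resident macrophages of the brain, made up 94.2% (92.0 to 95.9) of non-shocked, 97.1% (95.4 to 98.3) of acute non-helpless, 91.7% (89.4 to 93.7) of acute helpless and 91.2% (88.5 to 93.5) of chronic non-helpless cells. Their share was 81.8% (73.8 to 88.2) in the chronic non-recovered and 77.8% (73.8 to 81.5) in the chronic recovered library. T cells, the main lymphocytes found, made up 3.24% (1.96 to 5.02) of non-shocked, 1.54% (0.705 to 2.90) of acute non-helpless, 4.37% (2.97 to 6.18) of acute helpless and 4.57% (2.98 to 6.67) of chronic non-helpless cells. They reached 12.4% (7.11 to 19.6) in the chronic non-recovered and 13.2% (10.3 to 16.5) in the chronic recovered library. Within the non-shocked library, T cells were 3.13% (0.858 to 7.81) of batch 2 and 3.28% (1.84 to 5.34) of batch 3 cells. Monocytes made up 2.93% (1.61 to 4.87) of chronic recovered, 2.38% (1.27 to 4.03) of chronic non-helpless and 0.826% (0.0209 to 4.52) of non-recovered cells. They made up 0.512%, 0.683% and 1.02% of non-shocked, acute non-helpless and acute helpless cells. The 1 non-recovered monocyte barcode had 4166 of its 8312 UMIs in 7 neutrophil genes. Monocyte barcodes of the chronic non-helpless (5356 of 10728 and 1833 of 3952) and recovered libraries (4847 of 18402) also held many such UMIs. NK cells made up 3.35% (1.93 to 5.38) of recovered, 2.48% (0.514 to 7.07) of non-recovered and 1.37% (0.591 to 2.67) of non-shocked cells, and 0.914%, 0.171% and 0.873% of chronic non-helpless, acute non-helpless and acute helpless cells. Microglial markers were also found in 11 of the 16 recovered and in 20 of all 39 NK cell barcodes. B cells and other macrophages numbered at most 6 and 9 cells per library. All shares are shares of sorted CD45-positive cells, and the median depth ran from 2814 UMIs per cell in the non-recovered to 4839 in the recovered library.

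Most barcodes of the T cell class also carried microglial RNA. Of the 161 T cell barcodes, 117, or 72.7% (65.1 to 79.4), had at least 0.5% of their UMIs in 7 microglial markers, among them P2ry12 and Tmem119. The share was 56 of 63 in the chronic recovered library and 4 of 15 in the chronic non-recovered library. Without these barcodes, the T cell class made up 9.40% (4.79 to 16.2) of the chronic non-recovered library and 1.66% (0.669 to 3.39) of the chronic recovered library. Not all barcodes left held T cell receptor complex UMIs, whose median in them was 3 in the non-recovered and 0 in the recovered library. At least 2 such UMIs were found in 11 of the 15 non-recovered T cell barcodes, 4 of them mixed. In the recovered library they were found in 55 of the 63, 52 of them mixed. The shares then were 1.05% in non-shocked, 0.173% in acute non-helpless, 2.09% in acute helpless and 0.949% in chronic non-helpless cells. The T cell share of the recovered library therefore rested on the mixed barcodes, and that of the non-recovered library, from 15 cells, mostly did not.

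**Figure D1:**
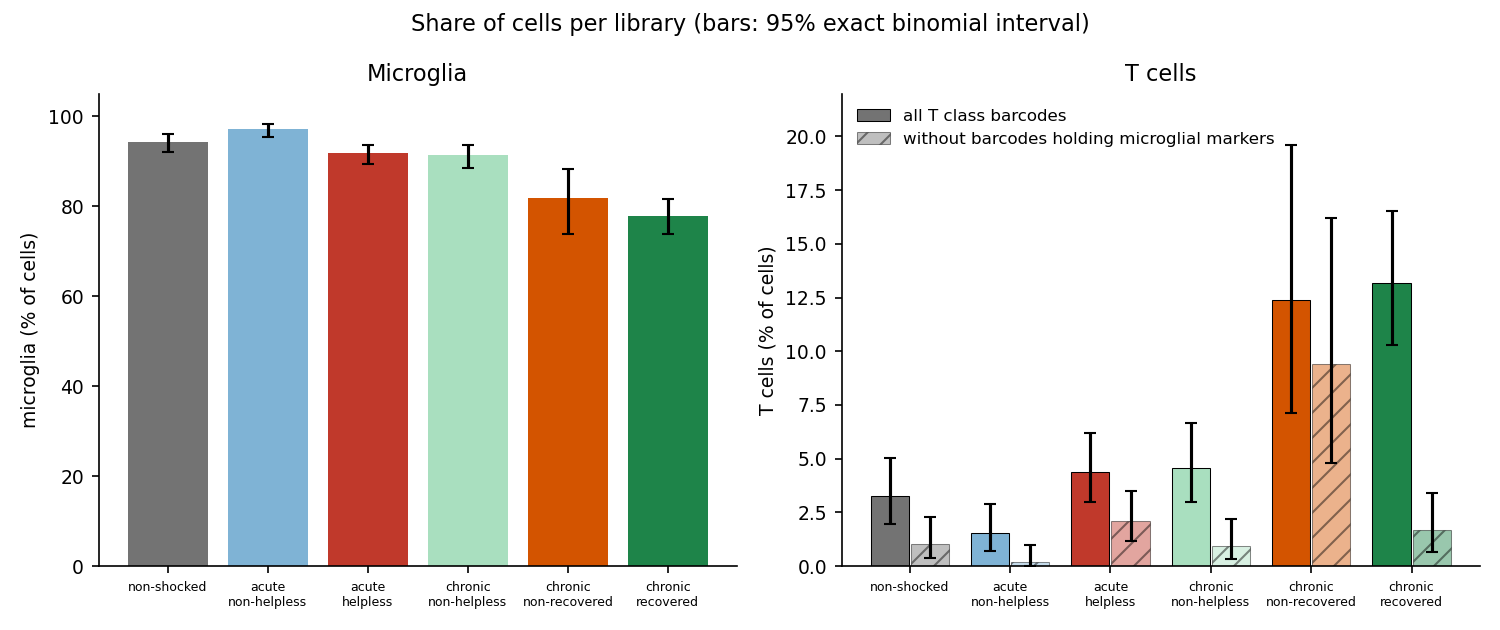
Share of cells (%) called microglia (left) and T cells (right) by the authors in each of the 6 libraries, with exact 95% binomial intervals as error bars. Hatched bars leave out T cell barcodes with at least 0.5% microglial marker UMIs, which takes the chronic recovered library from 13.2% to 1.66% and the chronic non-recovered library from 12.4% to 9.40%.

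**Figure D2:**
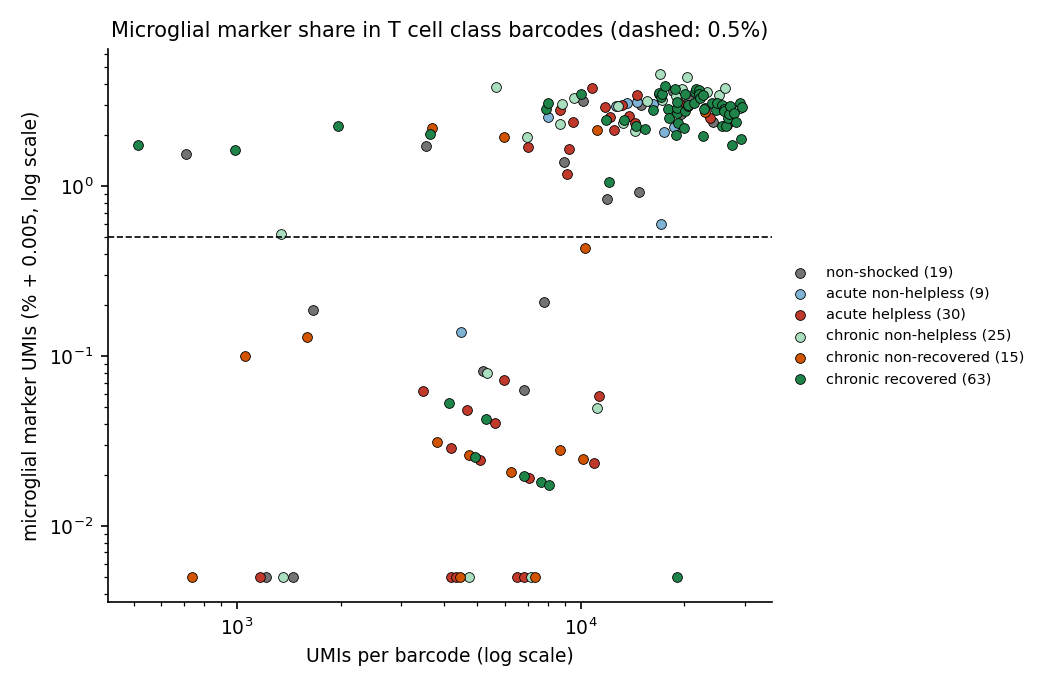
UMIs per barcode (log scale) against the share of UMIs in 7 microglial markers (%, log scale, 0.005 added) for the 161 T cell barcodes, coloured by library. Above the dashed line at 0.5% lie 117 barcodes, 56 of them from the chronic recovered library.

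The acute comparison asks how microglia of mice that became helpless differ from those of mice that did not after the same shocks. Microglia of the acute helpless library held fewer transcripts of inflammatory chemokines, immediate early genes and heat shock proteins and more of a pair of glucocorticoid-induced genes than those of the acute non-helpless library. These libraries were in different batches, so group and batch cannot be told apart here. Fkbp5, a co-chaperone of the glucocorticoid receptor that glucocorticoids induce, was 8.27-fold higher (6.51 to 10.7; 732 against 74 UMIs), and Ddit4, a stress-induced inhibitor of mTORC1, 3.61-fold higher (3.33 to 3.92; 3166 against 733). The chemokine genes Ccl4 and Ccl3 were 4.09-fold (3.25 to 5.20) and 3.10-fold (2.24 to 4.36) lower. Fosb and Fos, subunits of the AP-1 transcription factor, were 11.7-fold (7.35 to 19.5) and 3.47-fold (3.02 to 3.98) lower, and the inducible chaperones Hspa1b and Hspa1a 10.4-fold (6.48 to 17.8) and 8.84-fold (7.06 to 11.2) lower. Cebpb, a transcription factor of myeloid cells, was 12.6-fold higher (10.2 to 15.7).

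Of the 19 lists with enough measured members, 7 lay outside the central 95% of random lists, where random draws of genes give 0.95. Inflammatory cytokines and chemokines had a median log2 ratio of -0.79 (percentile 0, 4 of 8 members at least 1.5-fold lower), although its member Tgfb1 was 2.10-fold higher (1.92 to 2.29). Immediate early and dissociation genes had a median of -0.64 (percentile 0, 9 of 16 lower), with Dusp1 2.78-fold and Junb 1.90-fold lower and Klf4 5.35-fold higher (3.09 to 9.93). Genes of this list also respond to tissue dissociation, and what dissociation added to this and the other lists was not tested. Heat shock genes had a median of -0.43 (percentile 0, 5 of 16 lower) and NF-kB feedback and target genes a median of -0.35 (percentile 0.32, 5 of 14 lower), including Nfkbiz and Tnfaip3 at 2.97-fold and 2.12-fold lower. The glucocorticoid response list had a median of 0.17 (percentile 98.4), with 2 members at least 1.5-fold higher and 3 lower. Lysosome and phagocytosis genes had a median of 0.24 (percentile 100), with Lamp1 at 6.87-fold (6.23 to 7.57) higher. Growth factors and resolution genes had a median of -0.39 (percentile 0.78), though 4 members were at least 1.5-fold higher and 3 lower.

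Homeostatic microglial genes had a median of 0.082 (percentile 96.3), and none of their 20 members lay 1.5-fold apart. Medians of the other lists were 0.094 for disease-associated microglia, -0.29 for MHC class II presentation, -0.042 for MHC class I presentation, 0.094 for complement and Fc receptors and 0.038 for purinergic and neurotransmitter sensing. They were 0.10 for glycolysis and hypoxia, 0.013 for oxidative phosphorylation, -0.15 for mitochondrially encoded genes, 0.30 for proliferation, -0.041 for lipid and cholesterol handling and 0.033 for the Th17 and IL-17 axis. Across 3565 genes the median difference was 1.16-fold, and counting error alone gives 1.06-fold. Deposited cluster 1 held 46.2% of acute helpless and 41.1% of acute non-helpless microglia, and cluster 5 held 0 and 21.3%. In Leiden clustering the libraries parted, with acute helpless cells making up 98.2% of a cluster of 541 cells and acute non-helpless cells 96.8% of a cluster of 504. No cells of these groups shared a batch. Non-shocked microglia of batch 2 and batch 3, which belong to 1 group, differed by a median of 1.43-fold. Between them inflammatory cytokines and chemokines had a median of -1.24 and immediate early and dissociation genes -1.33, both larger than in the acute comparison.

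Dlgap1, a postsynaptic scaffold gene, was at least 181-fold lower in acute helpless microglia (0 against 455 UMIs), and Qpct, a glutaminyl cyclase, 86.1-fold lower (51.1 to 158). Both were also near or at 0 in chronic non-helpless microglia and in non-shocked microglia of batch 3, so these folds do not follow helplessness, and the genotype of the mice was not tested. Of the 12 genes with the highest ratio, 9 belonged to a group of 193 genes, Lamp1, Cebpb, Bri3, Arf5 and Ctbp1 among them, whose levels part the 6 libraries in a way that the batch numbers do not follow. In this group each of non-shocked batch 3, acute helpless and chronic non-recovered microglia was at least 1.5-fold above each of the other 3 libraries, with a median difference of 3.32-fold. Found without non-shocked cells, the group had 206 genes, and in these batch 3 and batch 2 of non-shocked microglia lay above the mean of the 3 lower libraries by a median log2 of 1.72 and 1.13. No other split of the libraries into 3 and 3 had more than 7 such genes. Fkbp5 and Ddit4 were not in the group.

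**Figure D3:**
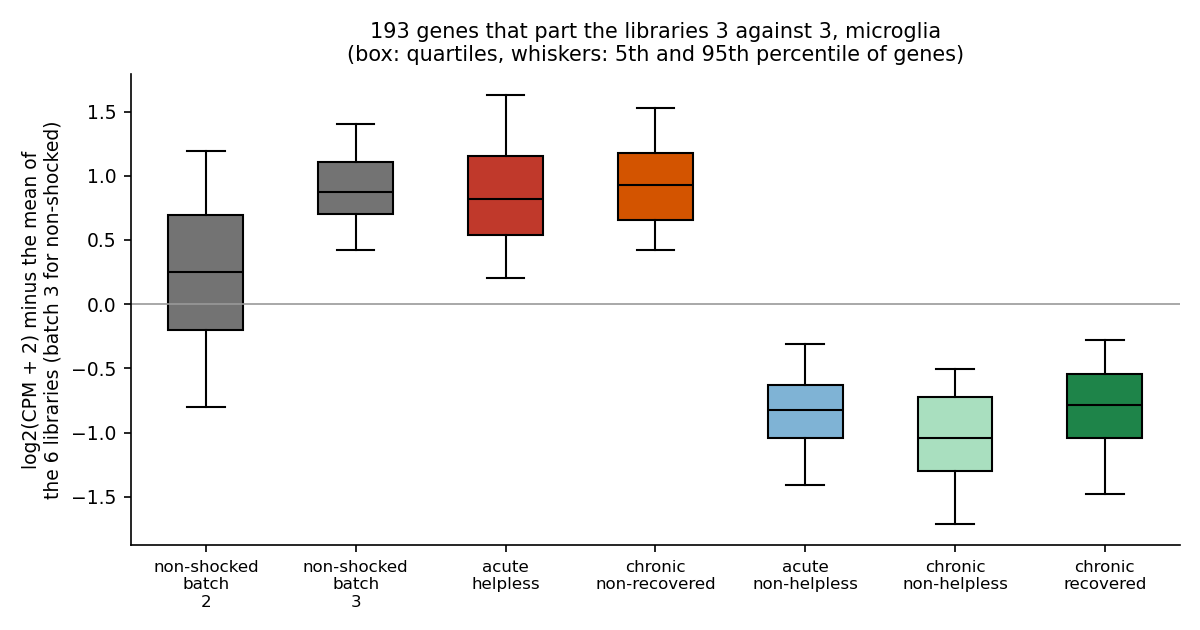
Level of the 193 genes in microglia of each library, as log2 of CPM plus 2 minus the mean of the 6 libraries (batch 3 for non-shocked), with non-shocked cells drawn by batch; boxes are quartiles and whiskers the 5th and 95th percentile of genes. Non-shocked batch 3, acute helpless and chronic non-recovered microglia lie above the other 3 libraries by a median of 3.32-fold, and non-shocked batch 2, not used to define the group, lies between.

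The comparisons with non-shocked mice ask what the shocks and the test themselves were followed by. Both acute libraries held more Ddit4, Tsc22d3 and heat shock transcripts than non-shocked microglia. Ddit4 was 42.1-fold higher (32.0 to 56.4) in acute helpless and 11.6-fold higher (8.79 to 15.7) in acute non-helpless microglia, and Tsc22d3, a glucocorticoid-induced leucine zipper protein, 8.78-fold (7.09 to 10.99) and 6.27-fold (5.03 to 7.88). Against non-shocked microglia of batch 2 alone, neither gene was among the 12 highest ratios of the acute non-helpless library. The last of those 12 was 5.28-fold higher, so within batch 2 Ddit4 lay below the interval of its 11.6-fold ratio. Hspa1a was 12.96-fold higher (9.45 to 18.2) in acute non-helpless microglia, at 284 CPM, while acute helpless microglia had 32.1 CPM and non-shocked microglia 21.9 CPM. Fkbp5 was 5.68-fold higher (4.55 to 7.16) in acute helpless microglia and at 32.6 CPM in acute non-helpless against 47.5 CPM in non-shocked microglia. Egr1, an immediate early gene, was 5.10-fold lower (4.43 to 5.88) in acute helpless and 4.91-fold lower (4.24 to 5.71) in acute non-helpless microglia. The latter reverses within batch 2, where non-shocked microglia had 34.4 CPM (12.6 to 74.9) and acute non-helpless microglia 98.4 CPM. The acute helpless fold used the same pooled non-shocked cells and depends on them as well, and no non-shocked cells shared its batch.

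In acute helpless against non-shocked microglia, heat shock genes had a median log2 ratio of 0.60 (percentile 100), oxidative phosphorylation genes 0.41 (percentile 100) and proliferation genes 0.52 (percentile 99.5). Only 5 of the 20 proliferation genes were measured, and 2 of them were at least 1.5-fold higher. Immediate early and dissociation genes had -0.80 (percentile 0, 11 of 16 at least 1.5-fold lower), inflammatory cytokines and chemokines -1.01 (percentile 0.030), NF-kB feedback and targets -0.60 (percentile 0.32) and purinergic and neurotransmitter sensing genes -0.28 (percentile 2.35). With each cell weighted equally these 3 medians were -0.36, -0.46 and -0.19, all inside the central 95%, and the purinergic list also came inside it under 5 other alternatives. In acute non-helpless microglia, heat shock genes had 1.14 (percentile 100, 14 of 16 at least 1.5-fold higher), oxidative phosphorylation genes 0.48 (percentile 100) and purinergic and neurotransmitter sensing genes -0.32 (percentile 1.08). Against the 123 non-shocked microglia of the same batch, the acute non-helpless library gave 0.95 for heat shock and 1.03 for oxidative phosphorylation genes, both at percentile 100, but -0.18 for purinergic and neurotransmitter sensing genes (percentile 19.1). There, immediate early and dissociation genes reached 1.25 and glucocorticoid response genes 1.04, against -0.053 and 0.22 with all non-shocked cells. Those 123 cells were shallow, with a median of 905 UMIs, and 63.4% (54.3 to 71.9) of them had under 2.5% ribosomal protein UMIs. The share of such microglia was 40.4% (36.3 to 44.6) in the whole non-shocked, 8.79% (6.59 to 11.4) in the acute non-helpless and 15.9% (13.1 to 19.0) in the acute helpless library. Fos stood at 68.8 CPM in them and at 407 CPM in batch 3, and Egr1 at 529 CPM in batch 3, so the immediate early genes depend on which non-shocked cells are used. The acute libraries and batch 2 also carry older gene symbols than batch 3, and genes are named here after older and newer symbols were merged.

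**Figure D4:**
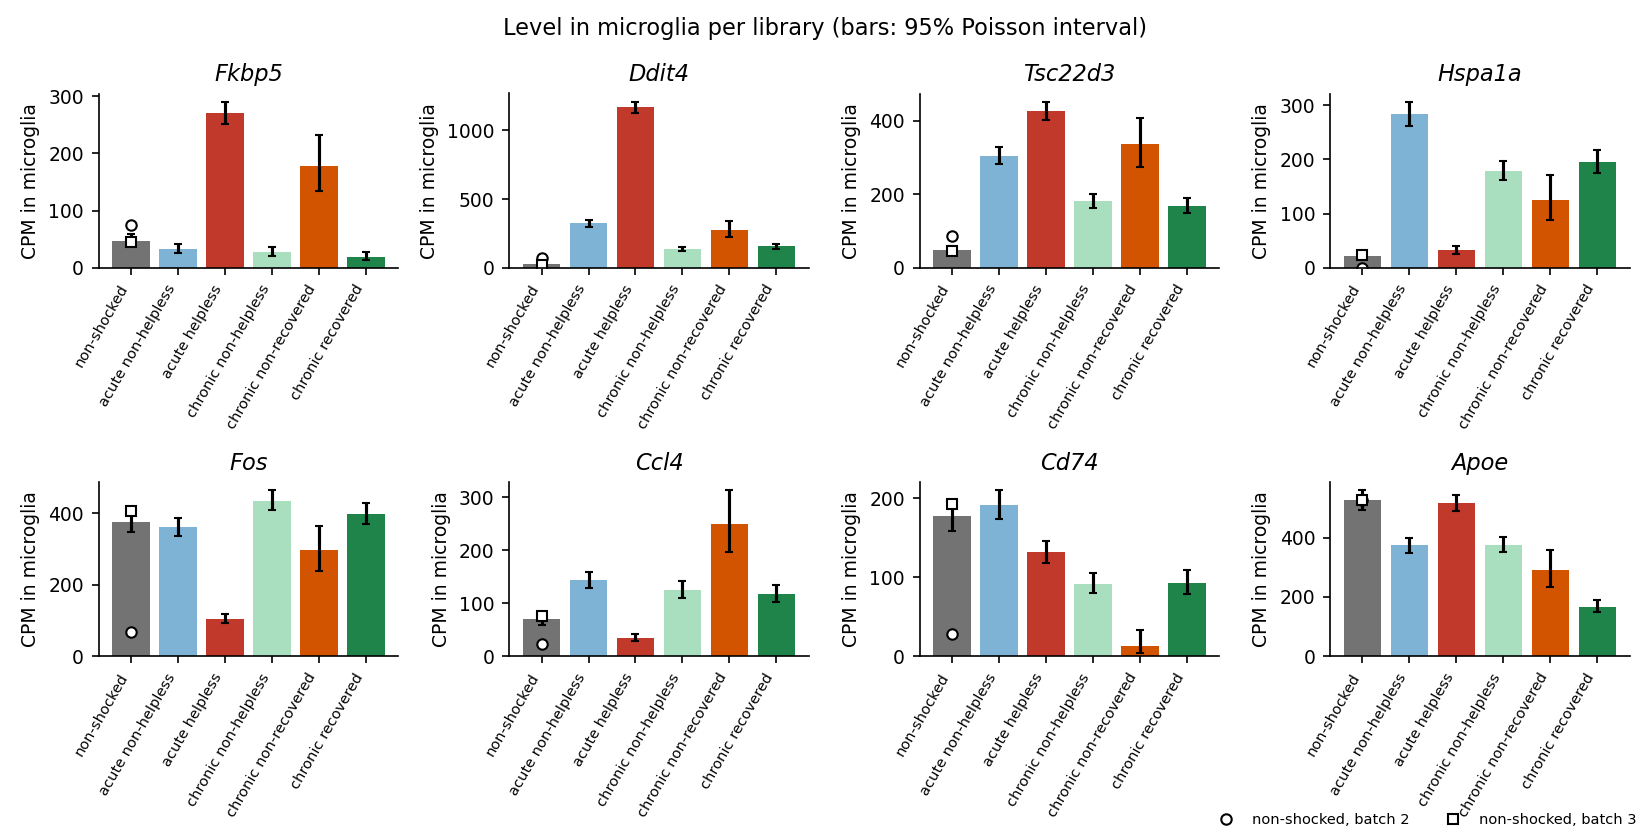
CPM in microglia of 8 genes in the 6 libraries, with 95% Poisson intervals as error bars; the circle and the square give non-shocked cells of batch 2 and batch 3. Fkbp5 stands at 270 CPM in acute helpless and 178 CPM in chronic non-recovered microglia and at 47.5 CPM or less in the other 4 libraries.

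The chronic comparison asks how microglia of mice that stayed helpless differ from those of mice that recovered, and both libraries were in batch 3. Chronic non-recovered microglia held more of several glucocorticoid-induced transcripts and fewer antigen presentation transcripts than chronic recovered microglia. Fkbp5 was 9.30-fold higher (5.92 to 14.8; 54 against 33 UMIs), Per1, a clock gene that glucocorticoids induce, 4.58-fold higher (2.59 to 8.02), and Tsc22d3 and Ddit4 1.99-fold (1.57 to 2.50) and 1.77-fold (1.37 to 2.27) higher. Cd74, the MHC class II invariant chain, was 7.08-fold lower (2.71 to 26.3; 4 against 161 UMIs), and the MHC class I genes H2-D1 and B2m were 1.99-fold (1.62 to 2.47) and 1.79-fold (1.51 to 2.14) lower. The Cd74 fold was smaller after the marker check given below. Ccl3 and Ccl4 were 2.88-fold (1.88 to 4.33) and 2.13-fold (1.61 to 2.78) higher, and Egr1 3.29-fold higher (2.58 to 4.18).

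Of 20 lists, 6 lay outside the central 95% of random lists, where random draws of genes give 1. MHC class II presentation and oxidative phosphorylation genes also lay outside it in non-shocked batch 2 against batch 3, at -0.75 and -0.62. MHC class II presentation had a median log2 ratio of -0.82 (percentile 0.080, 4 of 5 members at least 1.5-fold lower), MHC class I presentation -0.43 (percentile 0.64, 6 of 13 lower) and complement and Fc receptors -0.53 (percentile 1.35), with C1qb 1.60-fold lower (1.52 to 1.68). Oxidative phosphorylation genes had -0.50 (percentile 0, 8 of 20 lower), with Cox4i1 2.05-fold lower (1.56 to 2.74), and heat shock genes -0.49 (percentile 0.085, 6 of 15 lower). Lipid and cholesterol handling genes had 0.57 (percentile 98.2, 6 of 12 higher), including the lipid carrier Apoe at 1.73-fold (1.35 to 2.203) and the cholesterol exporter Abca1 at 1.72-fold (1.39 to 2.12). The glucocorticoid response list as a whole had a median of 0.039 (percentile 64.1), with 5 of 15 members at least 1.5-fold higher and 1 lower. Among the 5 was Lcn2, a neutrophil granule gene with 350 UMIs in non-recovered microglia. Nearly all UMIs of such genes in these microglia came from 1 barcode, as given below. Immediate early and dissociation genes had -0.033 (percentile 50.8), inflammatory cytokines and chemokines -0.10 (percentile 15.3) and homeostatic microglial genes -0.32 (percentile 25.7). Medians of the others were -0.26 for disease-associated microglia, -0.27 for the interferon response, -0.0028 for NF-kB feedback and targets, -0.29 for lysosome and phagocytosis and -0.20 for purinergic and neurotransmitter sensing. They were -0.25 for glycolysis and hypoxia, 0.12 for mitochondrially encoded genes, -0.019 for proliferation, 0.31 for the Th17 and IL-17 axis and 0.20 for growth factors and resolution.

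The non-recovered library had 99 microglia, and 52.5% (42.2 to 62.7) of them had under 2.5% ribosomal protein UMIs, against 9.41% (6.64 to 12.8) of the 372 recovered microglia. Deposited cluster 6 held 58.6% and cluster 1 held 41.4% of non-recovered microglia, while cluster 2 held 87.6% of recovered microglia. In microglia with at least 2.5% ribosomal protein UMIs, lipid and cholesterol handling genes had a median of 0.037 and complement and Fc receptors -0.29, both inside the central 95%, and with each cell weighted equally MHC class I presentation, at -0.44, also came inside. Across 2920 genes the median difference was 1.31-fold, counting error alone gives 1.12-fold, and the median log2 ratio of all these genes was -0.11.

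By the naming rule the highest ratios in this comparison belonged to neutrophil granule genes such as S100a9, S100a8, Ngp and Camp, and 6790 of the 6830 UMIs of 7 such genes in non-recovered microglia came from 1 barcode. Ttr, a choroid plexus transcript, was 127-fold lower (43.5 to 618), with 2122 of its 2171 UMIs in recovered microglia also in 1 barcode. After 15 barcodes of all microglia that failed a marker check were left out, the highest ratios were those of Btbd1 (19.1-fold, 10.3 to 37.8), Smap1 (10.4-fold, 6.64 to 16.6) and Fkbp5 (9.75-fold, 6.21 to 15.5). The lowest were those of Crlf2, a cytokine receptor chain, and Prdx4, a peroxiredoxin, at 4.25-fold (1.91 to 11.8) and 4.24-fold (1.61 to 15.9) lower. Cd74 was then 3.69-fold lower (1.39 to 13.9), with 88 UMIs in recovered microglia once 3 of their barcodes were left out. With merged symbols, 4 of the 12 genes named as higher belonged to the group of 193 genes, Btbd1 and Smap1 among them.

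Against chronic non-helpless microglia, which also were in batch 3, non-recovered microglia held 6.42-fold more Fkbp5 (4.35 to 9.45) and 6.99-fold less Cd74 (2.69 to 25.9). Apart from barcodes with neutrophil genes, the highest ratios were those of Dlgap1, at least 99.7-fold (41 against 0 UMIs), and Qpct, at 70.5-fold (30.5 to 200). Disease-associated microglia genes had a median log2 ratio of -0.62 (percentile 0.17, 7 of 12 at least 1.5-fold lower), with Cd9 and Tyrobp at 1.64-fold (1.44 to 1.88) and 1.54-fold (1.40 to 1.70) lower. MHC class II presentation had -0.76 (percentile 0.13), MHC class I presentation -0.37 (percentile 0.96), heat shock genes -0.43 (percentile 0.18), glycolysis and hypoxia -0.30 (percentile 0.89) and oxidative phosphorylation -0.40 (percentile 0.020). Proliferation genes had 1.32 (percentile 99.5), which became -0.45 after the marker check that removed the neutrophil-gene barcode. Monocyte entry and adhesion genes, measured in this comparison of microglia only, had 0.65 (percentile 93.5). In microglia with at least 2.5% ribosomal protein UMIs, the medians for heat shock, glycolysis and oxidative phosphorylation were -0.27, -0.096 and -0.14, all inside the central 95%.

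Recovered and chronic non-helpless microglia were the closest pair of the 9 comparisons, with a median difference of 1.10-fold over 3650 genes and 1.07-fold from counting error alone. Lipid and cholesterol handling genes were lower in recovered microglia, with a median of -0.37 (percentile 0, 4 of 12 at least 1.5-fold lower). Apoe was 2.25-fold lower (1.96 to 2.58) and Lpl, lipoprotein lipase, 3.08-fold lower (2.11 to 4.61). The myeloid transcription factors Cebpa and Cebpb were 3.99-fold (3.27 to 4.91) and 3.81-fold (2.81 to 5.25) higher, and Tgfb1 2.54-fold higher (2.29 to 2.83). Qpct was 20.0-fold higher (8.84 to 55.7). Of 20 lists, 4 others lay outside the central 95%, with medians between -0.13 and 0.20. In microglia with at least 2.5% ribosomal protein UMIs the lipid list remained outside the central 95%.

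All 3 chronic libraries held more heat shock transcripts and more of the glucocorticoid-induced Ddit4 than non-shocked microglia, and the non-recovered library held fewer MHC class II transcripts. The heat shock list had a median log2 ratio of 1.01 in chronic non-helpless, 0.57 in non-recovered and 1.06 in recovered microglia, each at percentile 100, and 1.02, 0.58 and 1.08 against non-shocked cells of the same batch. Hspa1a was 8.17-fold (5.91 to 11.6) higher in non-helpless and 8.89-fold (6.42 to 12.6) higher in recovered microglia. The glucocorticoid response list had 0.27, 0.38 and 0.29, and 0.21, 0.34 and 0.25 within batch 3, where the non-helpless value lay inside the central 95%. At least 1.5-fold higher were 4 of 15, 7 of 15 and 3 of 13 of its members, and with at least 2.5% ribosomal protein UMIs the non-recovered median was 0.17, inside the central 95%. Among the 7 was Lcn2, a neutrophil granule gene that 1 non-recovered barcode mostly supplied. Ddit4 was 4.97-fold (3.69 to 6.81), 9.96-fold (6.96 to 14.4) and 5.63-fold (4.17 to 7.73) higher in these libraries. Fkbp5 was 3.74-fold higher (2.62 to 5.30) in non-recovered microglia, but 1.72-fold (1.22 to 2.43) and 2.49-fold (1.65 to 3.83) lower in non-helpless and recovered microglia.

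MHC class II presentation genes had a median of -0.55 in chronic non-helpless, -1.63 in non-recovered and -0.44 in recovered microglia, and -0.60, -1.66 and -0.52 within batch 3. With each cell weighted equally, the medians for non-helpless and recovered microglia were -0.19 and 0.17, so that only the non-recovered value stayed outside the central 95%. At a minimum of 50 CPM they were -0.025 and 0.043. H2-Aa and H2-Eb1 had 0 UMIs in non-recovered microglia, at least 4.81-fold and 5.08-fold below non-shocked microglia. Oxidative phosphorylation genes had 0.25 in non-helpless, -0.18 in non-recovered and 0.36 in recovered microglia. Proliferation genes had 0.40 and 0.65 in non-helpless and recovered microglia, and 0.36 and 0.62 within batch 3, where only 5 and 7 of the 20 listed were measured. In non-recovered microglia their median of 1.89 became -0.12 after the marker check. Lipid and cholesterol handling genes had -0.35 in recovered microglia, with Apoe at 3.14-fold lower (2.75 to 3.59), but -0.042 and inside the central 95% in microglia with at least 2.5% ribosomal protein UMIs. In non-recovered microglia, MHC class I presentation had -0.29, complement and Fc receptors -0.35, disease-associated microglia genes -0.46 and lysosome and phagocytosis genes -0.26. In microglia with at least 2.5% ribosomal protein UMIs the last 3 were -0.25, -0.20 and -0.18, all inside the central 95%. Complement and Fc receptors had 0.027 with the mean in place of the median, and MHC class I presentation -0.14 with each cell weighted equally. Microglia with under 2.5% ribosomal protein UMIs made up 33.8% (29.3 to 38.5) of non-shocked batch 3, 15.6% (12.6 to 19.1) of chronic non-helpless, 52.5% of non-recovered and 9.41% of recovered microglia.

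**Figure D5:**
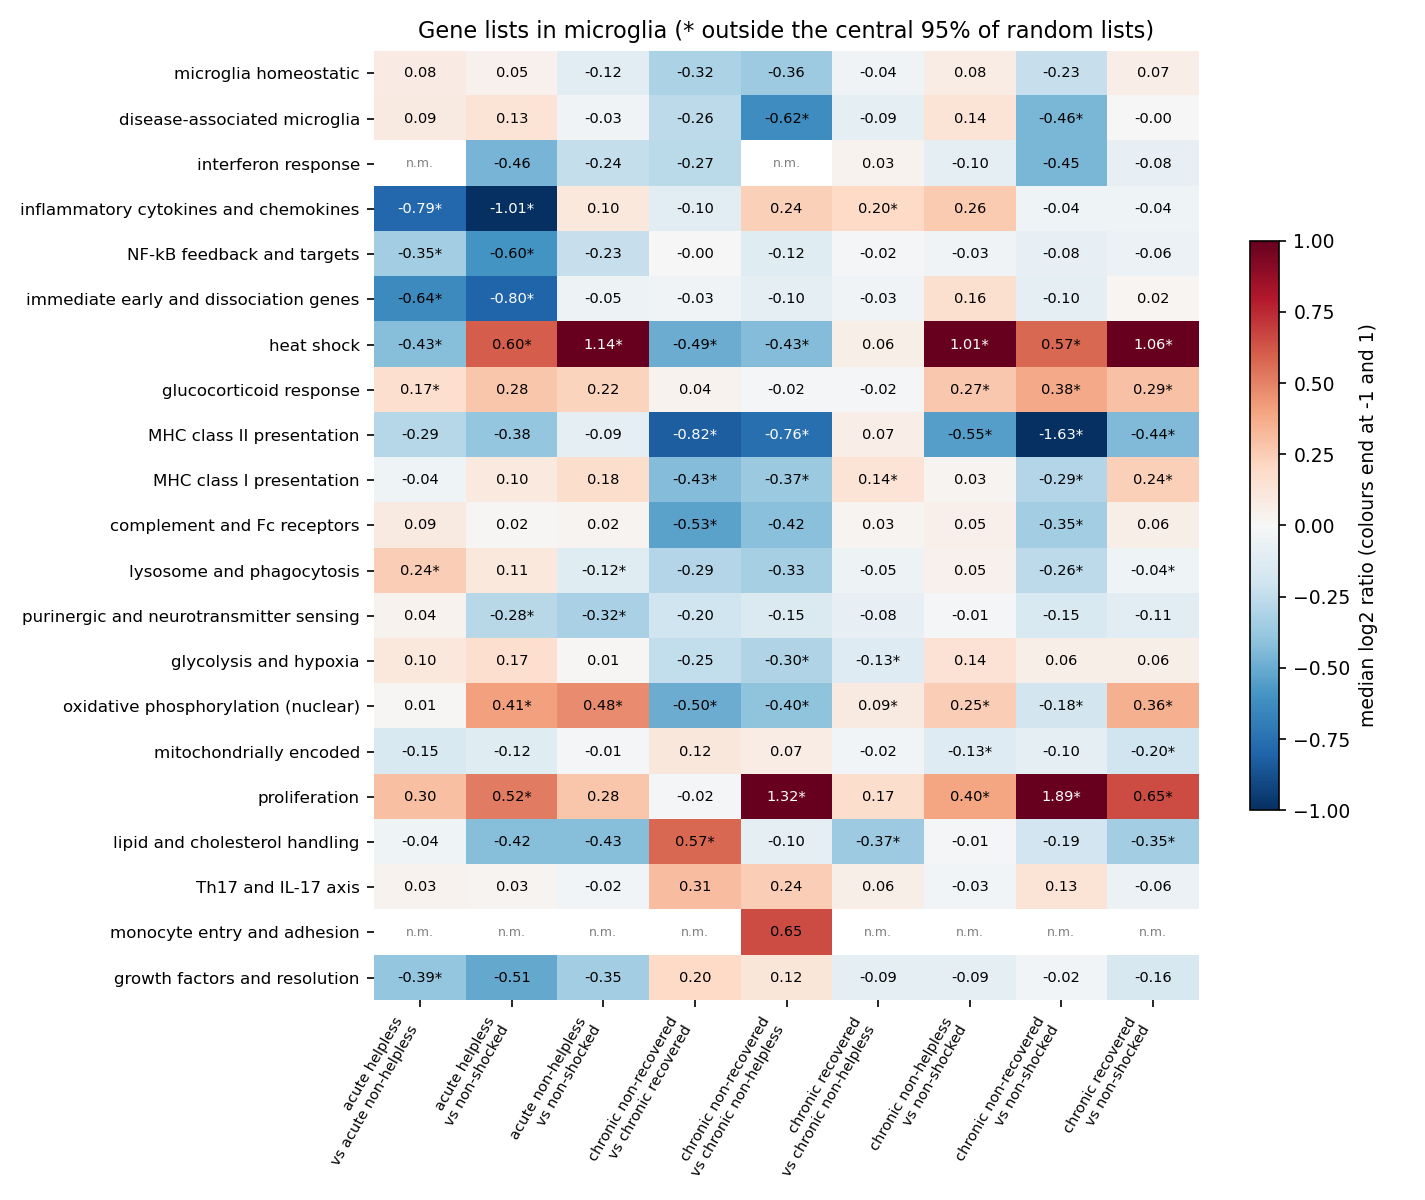
Median log2 ratio of each gene list (vertical axis) in microglia for the 9 comparisons (horizontal axis), coloured from -1 to 1. Asterisks mark the 60 of 179 values outside the central 95% of random lists, where random draws of genes give 8.95. The letters n.m. mark lists with under 5 measured members. Heat shock genes are at or above 0.57 in all 5 comparisons with non-shocked microglia.

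Among T cells, only 1 of the 9 comparisons had at least 20 barcodes in both libraries, that of recovered with chronic non-helpless mice, with 63 and 25. The acute helpless library had 30, but its comparisons were with libraries of fewer than 20. MHC class II presentation genes had a median log2 ratio of 1.84 (percentile 100) in recovered T cell barcodes, with Cd74 at 807 against 58.7 CPM. Inflammatory cytokines and chemokines had 0.43 (percentile 99.3), NF-kB feedback and targets 0.38 (percentile 99.9) and oxidative phosphorylation 0.17 (percentile 99.6). The interferon response had -0.43 (percentile 0.035), monocyte entry and adhesion -0.27 (percentile 0.865) and homeostatic microglial genes -0.11 (percentile 2.31). T cell activation and effector genes had -0.061 (percentile 37.2) and naive and recirculating T cell genes -0.042 (percentile 44.6). The costimulatory receptor gene Tnfrsf4 had 70 UMIs in recovered and 2 in non-helpless T cell barcodes. Most of these barcodes were mixed, since 56 of the 63 and 20 of the 25 held microglial markers. Which cells the MHC class II transcripts came from was not tested. Ttr, with 2553 UMIs, was again among the highest ratios. Of these UMIs, 2226 and 326 lay in recovered barcodes with only 0.0123% and 0% microglial marker UMIs and with 0 T cell receptor complex UMIs. The lowest ratios were those of the basophil genes Prss34 (0 against 422 UMIs) and Mcpt8 (0 against 54), so the chronic non-helpless T cell class held RNA of another cell type as well.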

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

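The tests of GC content, non-shocked batches, B cell barcodes, T cell UMIs and the Fkbp5 ratios other than the one with the ribosomal filter were chosen after the results were seen.

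A group of 193 of 4181 genes was higher in non-shocked batch 3, acute helpless and chronic non-recovered microglia, and the other 19 splits of the libraries into 3 and 3 gave at most 7. In 31 acute helpless and 23 chronic recovered barcodes of other cell types, the 113 of these genes that were measured had a median log2 ratio of 1.502 (1.20 to 1.82), near their 1.61 in microglia, which is consistent with an effect on whole libraries and not on microglia alone. GC content of the 5' end is higher in the group (69.3% against 59.3%), and 47 of the 202 genes in the highest of 20 GC bins belong to it, but genes matched on GC, members included, differed by only 0.098 (0.041 to 0.16), which argues against GC as the whole cause and leaves a part open. Cells with few ribosomal protein UMIs are argued against, since the difference without them was 1.74 against 1.73 with them. In the 206 genes found without non-shocked cells, batch 2 of these against batch 3 had a median log2 ratio of -0.58 (-0.70 to -0.48), against -0.11 (-0.22 to -0.00083) in genes matched on level, so the genes differ within 1 group of mice, but with 1 library per group the group of the mice and the library cannot be told apart.

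Microglial RNA in T cell barcodes may come from free RNA, from random pairs of cells or from T cells bound to microglia. Free RNA is argued against by B cell barcodes, whose median share of microglial markers was 0.00538%, against 2.54% in T cell barcodes with T cell receptor UMIs. Random pairs are argued against by barcodes with B cell receptor complex UMIs, of which 8.33% (1.75 to 22.5) held microglial markers, against 79.9% (72.5 to 86.0) of those with T cell receptor complex UMIs. Among the 133 T cell barcodes picked for having receptor complex UMIs, mixed barcodes held 0.95 times those of the others, but over all 161 the medians were 18 against 3, at 17480 against 5248.5 UMIs in all, so the ratio depends on the choice of barcodes and cannot tell bound cells from pairs that formed during dissociation. NK cell barcodes were mixed as well, 20 of 39 or 51.3% (34.8 to 67.6), so binding to microglia, in the tissue or after it, remains a hypothesis that is not specific to T cells.

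Fkbp5 was higher in microglia of both helpless libraries than of the other shocked libraries. Batch is argued against by the 9.30-fold ratio (5.92 to 14.8) of chronic non-recovered to recovered microglia within 1 batch, and few ribosomal protein UMIs by the 6.32-fold ratio (3.58 to 11.1) without such cells. The library split of the gene group is argued against as the whole cause by non-shocked cells of batch 3, which held 0.166 (0.129 to 0.210) of the acute helpless level. A part is left open, since Fkbp5 was also higher in non-shocked than in acute non-helpless, chronic non-helpless and recovered microglia. The acute ratio of 8.27 (6.51 to 10.7) cannot tell the group of the mice from their library and batch. A glucocorticoid response that lasts in helpless mice is a hypothesis, and other differences between the mice, such as the time of day or handling before dissection, were not tested. The glucocorticoid response list as a whole had a median of 0.039 (percentile 64.1) in non-recovered against recovered microglia. In the acute comparison it had 0.17 (percentile 98.4), with 2 members at least 1.5-fold higher and 3 lower.

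The genes below had opposite ratios in the acute and the chronic helpless comparisons, the smallest absolute log2 ratio being 1.09. They were picked out by their ratios alone, and genes with smaller opposite ratios are not listed. The difference between the paradigms was not tested. The log2 ratios were -1.63 and 1.53 for Ccl3, -2.03 and 1.09 for Ccl4, 3.11 and -2.17 for Crlf2, -7.50 and 2.51 for Dlgap1, and -6.43 and 1.76 for Qpct. Barcodes with at least 20 UMIs of neutrophil genes, of which non-shocked cells had 0, numbered 3 in the chronic non-helpless, 2 in the non-recovered and 1 in the recovered library. Barcodes with at least 50 UMIs of Ttr numbered 1 in the chronic non-helpless and 3 in the recovered library.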

How the results depend on the processing

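Same-batch non-shocked cells, merged symbols, the marker check, the ribosomal filter and leaving out mixed T cell barcodes were chosen after the data were seen. No paired analysis was possible because each group has 1 library and no pairing of mice is given. Below, values are percent of cells or log2 ratios, and the cause was not tested unless named. List medians counted here are those outside the central 95%, if in a main comparison or of a size of at least 0.25, and 8 others, a choice made after the data were seen. Of 473 alternative values of 57 list medians, 406 stayed on the same side of the central 95%, 51 came inside it, 7 left it and 9 changed sign. Median-of-ratios size factors left all 57 list medians, 9 spreads and 216 named genes in place, and totals without mitochondrial and ribosomal protein genes did so for the spreads and named genes. Both changes shift all genes of a comparison alike. The order of genes and, with size factors, the place of a list among random lists were therefore all but fixed in advance. For named genes, in place means only that the shifted ratio stayed within its main interval. The 57 list values are among the 406. Of 216 named genes, thinning moved 117, equal weighting of cells 77 and removing doublets 3. Removing doublets moved none of 36 shares. By the naming rule no Leiden cluster was microglia-like, so no Leiden value for microglia is given.

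Leiden clusters gave T cell shares of 5.46 in non-shocked, 4.27 in acute non-helpless, 6.26 in acute helpless, 7.50 in chronic non-helpless and 18.6 in recovered cells. Without mixed T cell barcodes the shares, in the same order, were 96.3, 98.4, 93.9, 94.7 and 88.2 for microglia and 1.05, 0.173, 2.09, 0.949 and 1.66 for T cells.

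With cells thinned to 1000 UMIs, Dcps (0.052, non-recovered against recovered), H2-Eb1 (0.97, non-recovered against non-shocked), and Retnlg and Ttr (1.27 and 0.75, non-recovered against chronic non-helpless) came out positive only because the 2, 0, 0 and 1 UMIs left in non-recovered microglia were set to 3, and their CPM stayed lower there, so none shows a change of direction. The median absolute difference of recovered and chronic non-helpless microglia was 0.24. With same-batch non-shocked cells, that of acute non-helpless microglia was 0.64, their purinergic median -0.18, immediate early 1.25 and glucocorticoid 1.04, both now outside the central 95%, and lysosome 0.24, a change of sign, and the glucocorticoid median of chronic non-helpless microglia 0.21.

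Merged symbols changed the sign of renamed genes, since each name had counts under 1 annotation. Against non-shocked microglia, acute helpless gave Rack1 0.42, Selenof 0.32, Selenok 0.48, Selenos 0.17 and Sem1 0.32, and acute non-helpless Rack1 0.53, Selenof 0.35, Selenok 0.48, Selenop 0.19, Selenos 0.12 and Sem1 0.36. Glucocorticoid genes had 0.23 in chronic non-helpless and 0.31 in acute non-helpless, the latter now outside, and purinergic genes in acute helpless -0.28.

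The marker check gave Enpp2 1.57 in non-recovered against recovered. With the neutrophil-gene barcode gone, proliferation was -0.45 in non-recovered against chronic non-helpless and -0.12 against non-shocked. Lysosome genes in non-recovered had -0.21 and purinergic genes in acute helpless -0.27 against non-shocked.

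With at least 2.5% ribosomal protein UMIs, non-recovered against recovered gave complement -0.29 and lipid 0.037. Non-recovered against chronic non-helpless gave glycolysis -0.096, heat shock -0.27 and oxidative phosphorylation -0.14. Against non-shocked, non-recovered gave complement -0.25, disease-associated microglia -0.20, glucocorticoid 0.17 and lysosome -0.18, recovered gave lipid -0.042, both acute libraries purinergic -0.17, and acute non-helpless glucocorticoid 0.25, now outside.

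With the mean in place of the median, acute helpless against acute non-helpless gave glucocorticoid 0.23 and growth factors 0.066, a change of sign. Against non-shocked, acute helpless gave NF-kB -0.74, inflammatory -0.81 and purinergic -0.26, and acute non-helpless purinergic -0.28 and lysosome -0.30. Non-recovered against recovered gave complement 0.0046, a change of sign, lipid 0.40 and glucocorticoid 1.01, now outside the central 95%. This glucocorticoid mean included Lcn2, a neutrophil granule gene that 1 non-recovered barcode mostly supplied. Non-recovered against chronic non-helpless gave glycolysis -0.11. Against non-shocked, non-recovered gave complement 0.027, a change of sign, heat shock 0.77 and lysosome -0.18, and recovered lipid -0.45.

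With each cell weighted equally, acute helpless against acute non-helpless gave glucocorticoid 0.079. Against non-shocked, acute helpless gave NF-kB -0.46, inflammatory -0.36 and purinergic -0.19, and acute non-helpless purinergic -0.21 and glucocorticoid 0.37, now outside. Non-recovered against recovered gave MHC class I -0.44, complement -0.50 and lipid 0.52, and against chronic non-helpless MHC class I -0.22 and proliferation -0.11, a change of sign. Against non-shocked, non-recovered gave MHC class I -0.14, complement -0.29, lysosome -0.27 and proliferation 0.55, chronic non-helpless MHC class II -0.19 and recovered MHC class II 0.17, a change of sign.

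A minimum of 5 CPM gave lysosome -0.12 in acute non-helpless against non-shocked, MHC class II -0.19 in chronic non-helpless against non-shocked, glycolysis -0.27 in non-recovered against chronic non-helpless, lipid 0.45 in non-recovered against recovered and purinergic -0.28 in acute helpless against non-shocked. A minimum of 50 CPM gave MHC class II -0.025 in chronic non-helpless and 0.043, a change of sign, in recovered against non-shocked, NF-kB -0.57 in acute helpless against non-shocked and lipid 0.40 in non-recovered against recovered. The homeostatic median of acute helpless against acute non-helpless stayed 0.082 and then lay outside the central 95%.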

Other observations

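All tests in this part were chosen after the results were seen. Fkbp5 transcripts were found in 65.6% (61.7 to 69.3) of acute helpless and 38.4% (28.8 to 48.7) of chronic non-recovered microglia, so its UMIs did not come from a few cells. The shares were 13.9% in non-shocked, 11.6% in acute non-helpless, 10.4% in chronic non-helpless and 8.06% in chronic recovered microglia. Depth differs between these libraries and adds to such shares, and the part that free RNA may add to them was not measured.

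Dlgap1 and Qpct lie on chromosome 17, from 69969073 to 70821413 and from 79051906 to 79090378. Dlgap1 was found in 49.7% of acute non-helpless microglia, 22.8% of non-shocked microglia of batch 2, 28.3% of chronic non-recovered and 8.60% of chronic recovered microglia. It was found in 0 of 630 acute helpless, 0 of 499 chronic non-helpless and 0 of 429 non-shocked microglia of batch 3. Qpct followed the same libraries, at 72.2%, 26.0%, 36.4% and 15.9%, and at 2.22%, 1.00% and 0.699% in the last 3. Microglia with both genes, against the number expected if the genes were independent, were 21 against 5.08 in the recovered and 15 against 10.2 in the non-recovered library, 11 against 7.28 in non-shocked batch 2 and 209 against 204 in the acute non-helpless library. Depth, which raises such counts, was not accounted for, and whether the mice of a library differed in genotype at these genes was not tested.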
